A study of Drosophila melanogaster with 3 samples.

How the data were processed

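The samples were 3 biological replicates of whole Drosophila melanogaster embryos of both sexes, aged 0 to 24 h, from a line expressing Chrac-16 with GFP at its C-terminus. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP. All 3 form 1 group, numbered by the biological replicate in the labels.

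The authors deposited peak lists in narrowPeak form for the dm6 and dm3 builds. Per the listings deposited beside them, each replicate has a relaxed list made as input for the IDR procedure. A pooled relaxed list was called on all 3 replicates together, and an optimal list was derived from the replicate and pooled lists. A control alignment entered the calling and is not analysed here. The peak caller and aligner are not given in the sources used here. The signal value of each peak is the authors' own, as deposited in column 7, and its scale differs between lists. It was used to rank, filter, describe and test peaks within a list, and between replicates to correlate them. The deposited −log10 q value of column 9 was read but entered no test. The deposited summit offset in column 10 gave the position of each peak. On both builds the optimal list was exactly the strongest part of the pooled list by signal, 4941 of 24641 peaks on dm6 and 4629 of 21570 on dm3. The list of replicate 1 on dm6 holds exactly 30000 peaks, which may be a ceiling on its length. Peak lists hold no read counts, so depth is unknown.

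Positions on dm6 were compared with the release 6 genome sequence and the Ensembl release 115 gene annotation of the same build. Transposable elements were left out. Chromosome Y, where the dm6 lists have no peak, was left out of every background. The dm3 lists were used for counts, overlaps and shares only, and no coordinate was carried between builds. Non-coding genes in the annotation include separate entries for mature microRNAs.

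A peak was at a promoter when its summit lay within 500 bp of a transcript start. Overlap needed 1 bp. Chance came from 1000 placements on the same arm, at bases other than N except for the overlap of replicates, where the whole arm was used. Shares have exact 95% binomial intervals, which cover counting error only. Gene lists, motifs and gene pairs were tested with Fisher's exact test, two-sided, and arms with an exact binomial test. The signal of promoter and other peaks was compared with 100000 permutations of the class labels. P-values were adjusted by the Benjamini-Hochberg method within each family, at a threshold of 0.05. Peaks and genes are not independent samples of embryos, so these p-values do not measure the spread between replicates, which is given as SD over the 3 replicates.

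The 31 gene lists, 21 motifs, main tests, most alternatives and the rule for named genes were set before the data were examined. Comparisons with moved peaks, with positions or promoters matched on GC content and with other non-coding genes, and the correlation across the pooled relaxed list, were added after the data were seen. The rule took all subunit genes, the 20 strongest promoter peaks and the 5 strongest other peaks found in all replicates, and the 3 members of highest signal in each developmental, Polycomb, insulator or significant list. After the data were seen, 7 outdated gene symbols in the lists were replaced by the current symbols of the same genes, before any list was tested. After first results, lists defined by symbol patterns were limited to protein-coding matches, as the planned background requires, which removed 12 other matches. Control promoters for motifs had no pooled relaxed summit within 500 bp, with 1 start per 500-bp cluster, and windows set at distances drawn from those of the promoter summits.

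The calculations were tested on simulated lists of 4941 peaks with known answers, built on the same genome. Simulated promoter share was recovered as 65.7% where 65.5% was expected, peaks found in 1 replicate as 85.3% of 85%, and ribosomal protein genes with a peak as 78.5% of 79.2%. A motif inserted at 30% of promoter summits was found at 31.3%, natural matches included. An early version of the control promoters called motifs that had not been inserted, and was corrected after real results had been seen. In the corrected version 1 of 19 motifs not inserted passed, with odds ratios from 0.711 to 1.67. Of 30 lists without enrichment, 4 passed Fisher's test, all 4 of them lists of RNA genes. Simulated promoter peaks were placed only at starts of protein-coding genes, so low counts for RNA genes were built in. With promoter peaks moved to random promoters, a comparison added after this result, 3 of the 30 still passed, again lists of RNA genes. These passes therefore do not show a bias of either comparison. A first run with moved peaks used 100 moves, too few for any list to pass, and was repeated with 1000 after the results were seen. Against other non-coding genes 0 of 4 RNA lists passed. Peaks found in all simulated replicates came out at 63.1% where 61.4% was expected. Gene pairs simulated without enrichment gave an odds ratio of 1.07, with a permutation p of 0.0769 against moved peaks.

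The alternatives tried were other distances, windows and overlaps, stricter and looser peak sets, other comparison sets, the other build, removal of summits in sequence over 50% soft-masked (3.60% of summits), and leaving out each replicate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. In the optimal list 5 intervals were repeated with other summits and were kept.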

Results

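Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Chrac-16 in whole embryos of Drosophila melanogaster. Chrac-16 is a small histone-fold subunit of CHRAC, a chromatin remodelling complex built around the ATPase Iswi and the protein Acf. The embryos were of both sexes, aged 0 to 24 h, and carried Chrac-16 fused to GFP, which was precipitated with an antibody against GFP. There was 1 group of 3 biological replicates and no second condition. The comparisons are therefore between replicates, between peaks and random positions, and between classes of genes. On the dm6 build the relaxed lists held 30000, 24619 and 29140 peaks in replicates 1, 2 and 3. The pooled relaxed list held 24641 peaks and the authors' optimal list, thresholded on the irreproducible discovery rate (IDR), held 4941. Read depth is unknown from peak lists. In the optimal list 457 peaks overlapped another peak of the list, so some sites were counted by more than 1 summit.

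The 3 replicates ranked largely the same sites highest. Among the 4941 strongest peaks of each replicate, 82.5% ± 0.144 (SD, n = 3 pairs) overlapped a strongest peak of the other replicate. Random placement on the same arm gave 2.68% to 2.69% (one-sided permutation test, adjusted p = 0.000999, the smallest that 1000 placements can give, in each of the 3 pairs). Across IDR peaks, Spearman's rho of signal between replicates was 0.808 for replicates 1 and 2, 0.824 for 1 and 3, and 0.831 for 2 and 3. Pearson's r of log2 signal was 0.856, 0.874 and 0.877 for the same pairs. The IDR list was derived from the replicate and pooled lists with a threshold on irreproducibility. It was exactly the 4941 strongest of the 24641 pooled peaks by signal. The threshold thus set the length of the list, and its peaks were not picked singly for agreement. The pooled list was called on these same replicates, and peaks are not independent replicates. Across the pooled relaxed list, not thresholded in this way, rho was 0.788, 0.791 and 0.801 for the same pairs, over the 59.8% to 64.8% of its peaks present in both replicates.

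Of the 4941 IDR peaks, 3684 (74.6%, exact 95% interval 73.3 to 75.8) overlapped one of the strongest peaks in all 3 replicates. The share in a single replicate was 89.3% ± 0.188 (SD, n = 3). The choice of peaks by pooled signal, drawn from these same replicates, may bear on these shares too. With the whole relaxed lists 4926 (99.7%) overlapped a peak in all 3. With the strongest peaks only, the share was 20.7% among the 1236 weakest IDR peaks and 99.8% among the 1235 strongest. Peaks ranked near the limit of 4941 can fall past it in a replicate, so this difference is in part built in. The intervals cover counting error only.

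Chrac-16 summits were concentrated at promoters and nearly missing from coding sequence. Within 500 bp of an annotated transcript start lay 2550 of the 4941 IDR summits (51.6%, exact interval 50.2 to 53.0), against 13.6% of random positions. That is a ratio of 3.79 (two-sided permutation test over 7 classes, adjusted p = 0.0014). In the replicates' strongest peaks the promoter share was 51.2% ± 0.993 (SD, n = 3). Coding exons away from promoters held 9 summits (0.182%, exact interval 0.0833 to 0.345), against 13.7% of random positions and 3.66% of random positions matched on GC content. Introns held 1585 summits (32.1% against 39.5% at random) and intergenic sequence 690 (13.96% against 27.1%), and 3' UTRs held 36 (0.729% against 4.43%, or 7.32% with GC matched). Each of these 4 classes was below random with an adjusted p of 0.0014 in the same permutation test. The 5' UTR call depends on the order in which classes are assigned: 20 summits lay there, at 0.513 times the random share, but at 2.12 times when exons and introns were assigned before promoters. The same order moved introns to 1.03 times. Non-coding exons held 51 summits, at 1.26 times the random share, which did not pass (permutation test, adjusted p = 0.109). With that order they were at 1.64 times and passed (permutation test, adjusted p = 0.00117).

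**Figure D1:**
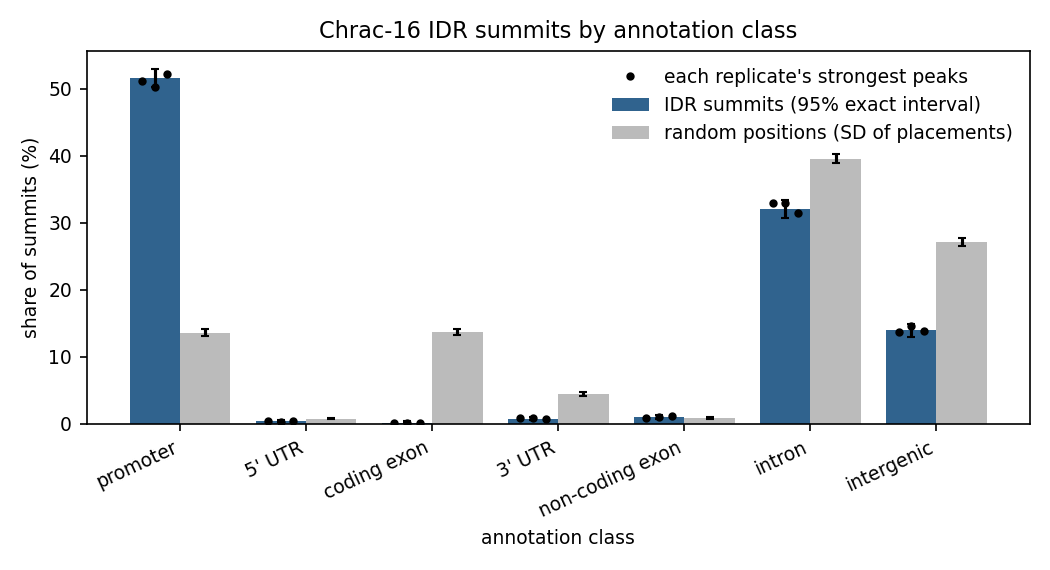
Share of IDR summits (blue bars, exact 95% intervals) and of random positions (grey bars, SD over 1000 placements) in each annotation class, in percent, with a black point for the strongest peaks of each of the 3 replicates. Promoters hold 51.6% of summits against 13.6% of random positions, and coding exons 0.182% against 13.7% (3.66% with GC matched).

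The promoter share was highest among the strongest peaks. It was 46.8% (exact interval 43.95 to 49.6) in the 1236 weakest IDR peaks, 46.6% and 51.9% in the next 2 sets of 1235, and 61.1% (exact interval 58.4 to 63.9) in the 1235 strongest. Among the 18904 pooled relaxed peaks that overlap no IDR peak it was 26.6%, lower than among IDR peaks (Fisher's exact test, two-sided, odds ratio 2.94, p = 2.76e-235). The median signal of promoter peaks was 1.15 times that of the other IDR peaks (186.3 against 162.5; two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). The ratio was above 1 in 3 of 3 replicates, at 1.16 ± 0.00957 (SD, n = 3).

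Promoter summits lay upstream of the transcript start. The median position was -107 bp, with quartiles of -193.8 and -41 bp, and 2147 of 2550 promoter summits (84.2%) were upstream. The median in the replicates was -104.3 ± 3.21 bp (SD, n = 3).

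**Figure D2:**
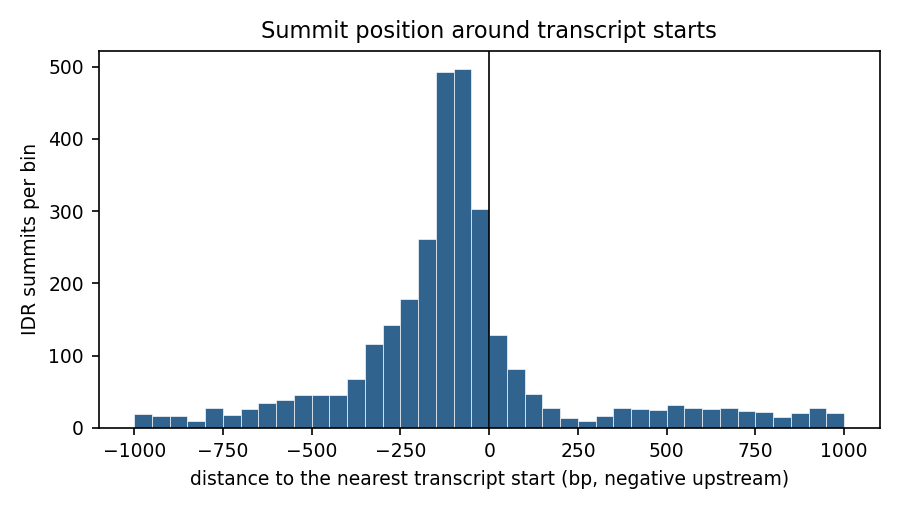
Number of IDR summits in 50-bp bins by distance to the nearest transcript start, in bp with negative values upstream, for summits within 1000 bp. The summits gather upstream of the start, with a median of -107 bp among those within 500 bp.

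The 20 strongest promoter peaks found in all 3 replicates had signal values from 1438 to 2820, and 15 of the 20 summits lay upstream of the nearest start. Of the 20, 10 lay within 500 bp of the starts of 2 genes, so the gene named is only the nearer one. The highest was 108 bp upstream of CG14100 (FBgn0036889; dm6, 3L, 19590405 to 19590825; signal 2820), with signals of 990, 917 and 936 in replicates 1, 2 and 3. It was followed by px at 2646 (FBgn0003175; 2R, 22514101 to 22514519, inside the gene) and the UDP-galactose transporter gene Ugalt at 2487 (X, 2703688 to 2704096). Chro, which encodes the chromodomain protein Chromator, had a signal of 2479 (3L, 22878697 to 22879119) with its summit 89 bp downstream of the start. The peak at Art3 reached 2211 (3R, 15229323 to 15229739). That at the Polycomb gene ph-p reached 2176 (X, 2137137 to 2137577), 479 bp upstream of the nearest start. The other 14 were at Tcs5, CenG1A, CG8320, CG1888, PNPase, mRpL41, larp, Pal1, CG5611, Shc, CG9147, gish, GstE13 and Sox14.

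The single strongest peak of the list and of every replicate was not at a promoter by this definition. It had a signal of 3155 and lay on 2L, 480876 to 481328, in an intron of ush, 1397 bp upstream of the nearest start, that of cbt. The other 4 strongest peaks away from promoters were in introns of CG11050 (signal 2022), Lk6 (1810) and HmgZ (1714), and in intergenic sequence 11930 bp from the start of CG13323 (1697).

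Of the genes for CHRAC and ACF subunits, 1 of 4 had a promoter IDR peak. This was Acf (3R, 31793617 to 31794032; signal 155.9, rank 2833 of 4941), at a site whose nearest start is that of Mccc1. Its signal was 46.01, 52.9 and 47.3 in the 3 replicates. The nearest IDR summits to starts of Iswi, Chrac-16 and Chrac-14 were 3160, 2816 and 25918 bp away. The 4 genes did not differ from other protein-coding genes (Fisher's exact test, odds ratio 1.15, adjusted p = 1), a test that 4 genes leave with an interval from 0.0219 to 14.3.

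Cytosolic and mitochondrial ribosomal protein genes carried promoter peaks more often than other genes. Among all protein-coding genes, 3137 of 13945 (22.5%) had one. Of 31 gene lists, 15 passed Fisher's exact test (two-sided, adjusted over the 31 lists), 7 above other genes and 8 below. The 7 lists above had odds ratios over 1 in the strongest peaks of 3 of 3 replicates, though splicing factors did not pass in replicate 2 alone (1.97, adjusted p = 0.166, Fisher's exact test) nor RNA polymerase II and general transcription factors in replicate 3 alone (1.81, adjusted p = 0.189). Cytosolic ribosomal protein genes led, with 57 of 93 (61.3%, odds ratio 5.54, 95% interval 3.58 to 8.67, adjusted p = 1.35e-14, Fisher's exact test), the strongest being RpL34b (signal 615.5), RpL7 (539.4) and RpS20 (518.3, at a site nearest to the start of CG17271). Among mitochondrial ribosomal protein genes 38 of 73 had a peak (52.1%, odds ratio 3.77, adjusted p = 1.56e-07, Fisher's exact test), with mRpS10, mRpS23 and mRpL41 strongest. The mRpS10 and mRpS23 peaks are the ones named above for Art3 and CenG1A.

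Insulator and architectural proteins had peaks at 11 of 20 genes (odds ratio 4.22, adjusted p = 0.00378, Fisher's exact test), with Chro at 2479, Cp190 at 863.6 (nearest start CG4338) and Trl, the GAGA factor gene, at 407.5. Other ISWI partners and chromatin remodellers had 16 of 31 (odds ratio 3.69, adjusted p = 0.00104, Fisher's exact test), led by brm (838.7), Ino80 (715.2) and pont (476.3). Splicing factors had 16 of 31 with the same odds ratio and adjusted p, led by U2af50 (419.3), SNRPG (374.6) and SF2 (374.1). The nearest starts to these 3 summits were those of PIG-Q, mthl1 and pad. Cell cycle and mitosis genes had 17 of 34 (odds ratio 3.46, adjusted p = 0.00146, Fisher's exact test), led by Dp (488.1), cnn (368.7) and SAK (358.3, nearest start Cdk12). RNA polymerase II and general transcription factors had 15 of 38 (odds ratio 2.25, adjusted p = 0.0376, Fisher's exact test), led by Polr2H (587.4, nearest start CG11247), Polr2B (554.5) and Taf5 (425.1). With the 50% of peaks of higher signal, the odds ratios of these last 4 lists were 2.65, 2.65, 2.70 and 2.31 and none passed (adjusted p from 0.0530 to 0.0644, Fisher's exact test). With peaks found in all 3 replicates, remodellers (2.22, adjusted p = 0.105, Fisher's exact test), cell cycle genes (2.23, adjusted p = 0.0802) and RNA polymerase II genes (2.16, adjusted p = 0.0768) did not pass. With peaks required in only 2 replicates' strongest sets, the remodellers and the splicing factors did not pass without replicate 1 (odds ratio 2.36, adjusted p = 0.0716, Fisher's exact test, for both) or without replicate 3 (2.38, adjusted p = 0.0703), cell cycle genes without replicate 3 (2.36, adjusted p = 0.0586), and RNA polymerase II genes without replicate 1 or 2 (1.98, adjusted p = 0.116). The RNA polymerase II list also did not pass at 1000 bp (2.14, adjusted p = 0.0534, Fisher's exact test) or without soft-masked summits (1.47, adjusted p = 0.454).

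**Figure D3:**
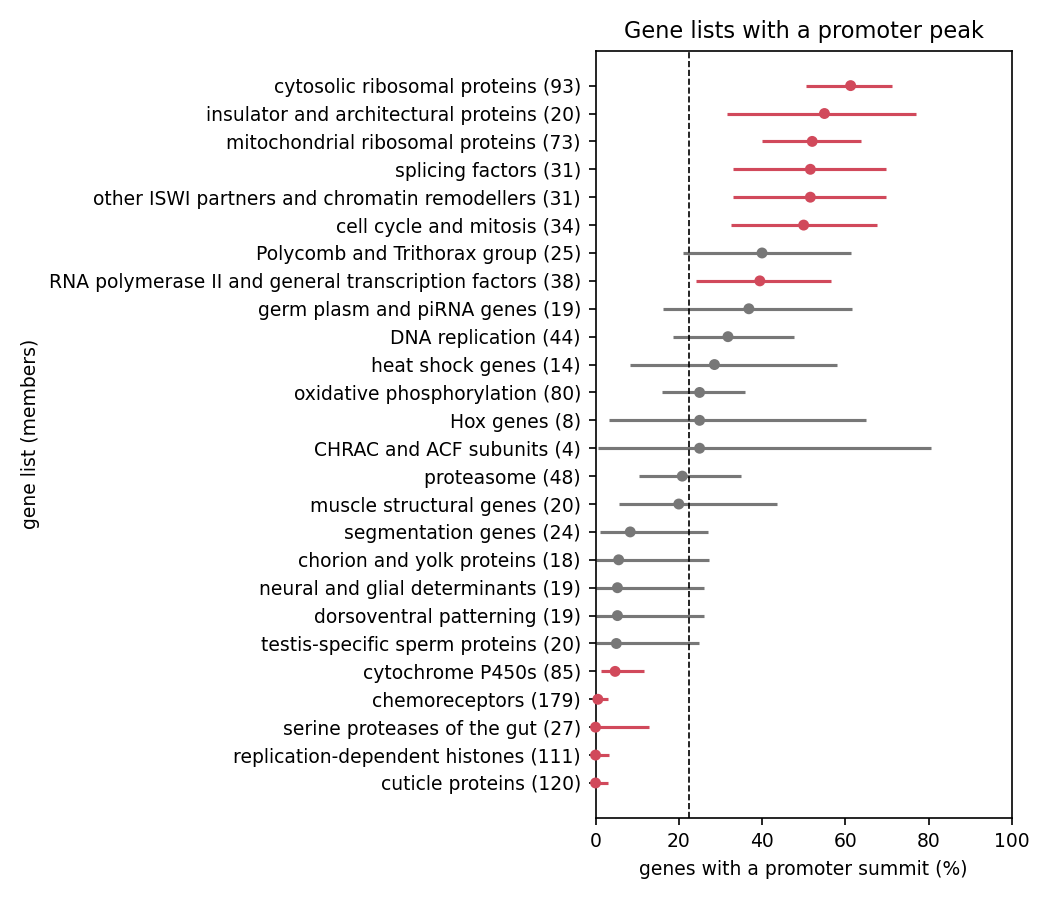
Share of each protein-coding gene list with a promoter IDR summit, in percent, with exact 95% intervals; red marks lists past Fisher's exact test after adjustment, and the dashed line is all protein-coding genes (22.5%). Cytosolic ribosomal protein genes are highest at 61.3%, and cuticle protein, replication-dependent histone and gut serine protease genes are at 0.

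Polycomb, Hox, segmentation, dorsoventral and neural gene lists did not pass the main test. Polycomb and Trithorax group genes had peaks at 10 of 25 (odds ratio 2.30, adjusted p = 0.0997, Fisher's exact test), with ph-p at 2176, E(z) at 619.9 and Sfmbt at 271.8. This list did pass when promoter peaks were moved to random promoters (permutation test, adjusted p = 0.0289), when genes sharing a promoter were counted once (odds ratio 4.09, adjusted p = 0.00187, Fisher's exact test), in the pooled relaxed list (4.05, adjusted p = 0.00456) and in replicate 3 alone (3.77, adjusted p = 0.00274). It did not in replicate 1 (2.00, adjusted p = 0.154, Fisher's exact test) or 2 (2.01, adjusted p = 0.171) alone, and its odds ratio was 1.47 with peaks found in all replicates (adjusted p = 0.531), 1.62 with the 50% of peaks of higher signal (adjusted p = 0.606) and 1.35 to 2.02 without 1 replicate (adjusted p from 0.207 to 0.563). The Polycomb pass with moved peaks has a limit. Moved peaks reached a mean of 2438 protein-coding genes against 3137 observed, so lists of protein-coding genes tend to exceed them. Polycomb genes were at 2.03 times their moved mean, and proteasome genes, which did not pass, at 1.38 times. Hox genes had 2 of 8, Dfd (142.3) and Antp (101.9). Segmentation genes had 2 of 24, bcd (424.9) and nkd (414.3). Dorsoventral patterning genes had 1 of 19, tin (373.9), and 0 of 19 without soft-masked summits, which passed (adjusted p = 0.0408, Fisher's exact test). Neural and glial determinants had 1 of 19, elav (901.8).

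Cuticle protein, chemoreceptor and cytochrome P450 genes carried promoter peaks less often than other genes. Cuticle protein genes had peaks at 0 of 120 (exact interval up to 3.03%, adjusted p = 6.54e-13, Fisher's exact test) and chemoreceptor genes at 1 of 179 (adjusted p = 2.88e-17), Ir60e, at a site nearest to the start of CG13585. Cytochrome P450 genes had 4 of 85 (odds ratio 0.169, adjusted p = 3.73e-05, Fisher's exact test), with Cyp6u1 (814.5), Cyp9f2 (141.7) and Cyp317a1 (125.04) strongest. The Cyp6u1 and Cyp9f2 peaks were nearest to the starts of Ufsp1 and CG5167. Gut serine protease genes had 0 of 27 (adjusted p = 0.00405, Fisher's exact test), a call lost when promoter peaks were moved to random promoters (permutation test, adjusted p = 0.0880) and with the 50% of peaks of higher signal (adjusted p = 0.0869, Fisher's exact test). The count was 0 of 27 with those peaks too, and moved peaks gave a mean of 3.91. Replication-dependent histone genes, a list of another kind, had 0 of 111 (adjusted p = 5.46e-12, Fisher's exact test), but these are near-identical repeated copies where reads cannot be placed with certainty, so their count is uncertain.

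The tRNA, snoRNA and microRNA genes were also below all other genes in Fisher's exact test, with 14 of 290, 11 of 269 and 8 of 260 (odds ratios 0.218, 0.183 and 0.136). That comparison is mostly with protein-coding genes. Simulated promoter peaks were placed only at starts of protein-coding genes, and there the same 3 lists came out at 0.242, 0.119 and 0.171. Low values were thus built into the simulation, which cannot show whether the real ones reflect the test alone. Against the other non-coding genes none of these 3 lists passed (odds ratios 0.769, 0.642 and 0.473; adjusted p = 0.444, 0.249 and 0.0642, Fisher's exact test), while snRNA genes were above them (4.41, adjusted p = 0.0103). All 3 lists were below promoter peaks moved to random promoters, at 0.348, 0.375 and 0.221 times their number (permutation test, adjusted p = 0.0031, 0.0406 and 0.00516). The same simulation gave 0.335, 0.214 and 0.237, with the same limit. In the pooled relaxed list 124 of 290 tRNA genes had a peak, near the share of all other genes (odds ratio 0.9502, adjusted p = 0.724, Fisher's exact test) and above that of other non-coding genes (2.40, adjusted p = 3.19e-11). The snoRNA call was lost at 1000 bp (0.8003, adjusted p = 0.270, Fisher's exact test) and with genes sharing a promoter counted once (0.883, adjusted p = 0.745). The members with the highest signal were tRNA:Tyr-GTA-1-8 (736.9), tRNA:Gln-TTG-2-1 (408.7) and tRNA:His-GTG-1-3 (323.3), snoRNA:Psi28S-2949 (395.8), snoRNA:Psi18S-1275 (324.5) and snoRNA:Or-CD13 (310.6), and mir-9377 (374.4), mir-4974 (160.01) and mir-ban (156.4). Several of these sites were nearest to another gene's start, such as that of Uhg4 for snoRNA:Psi28S-2949. The remaining lists, which did not pass the main test, had 14 of 44 for DNA replication, 20 of 80 for oxidative phosphorylation, 10 of 48 for the proteasome, 4 of 20 for muscle structural genes, 1 of 18 for chorion and yolk proteins, 1 of 20 for testis-specific sperm proteins, 4 of 14 for heat shock genes, 7 of 19 for germ plasm and piRNA genes, 0 of 7 for dosage compensation and 7 of 32 for snRNA genes. Some of these passed under an alternative. DNA replication genes passed in the pooled relaxed list (3.04, adjusted p = 0.00158, Fisher's exact test) and with moved peaks (permutation test, adjusted p = 0.0143). The limit given above for moved peaks holds for them too. Germ plasm and piRNA genes passed with shared promoters counted once (3.22, adjusted p = 0.0282, Fisher's exact test). Chorion and yolk protein genes passed in the relaxed list (0.202, adjusted p = 0.0129, Fisher's exact test). Testis-specific genes passed in the relaxed list (2 of 20, 0.112, adjusted p = 0.000887, Fisher's exact test), and with 0 of 20 without soft-masked summits (adjusted p = 0.0255), in replicate 3 alone (adjusted p = 0.0240) and without replicate 2 (adjusted p = 0.0451).

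Head-to-head gene pairs carried peaks more often than other genes. Of 4562 protein-coding genes whose start lay within 1000 bp of an oppositely oriented start, 1842 (40.4%) had a promoter peak, against 1295 of 9383 others (13.8%; Fisher's exact test, two-sided, odds ratio 4.23, p = 6.12e-259). A single peak can serve both genes of such a pair, so the genes are not independent. Promoter peaks moved to randomly drawn genes gave an odds ratio of 1.80, at most 2.14 in 1000 moves, and peaks moved to random clusters of starts gave 1.00, at most 1.19. The observed value was above both (permutation p = 0.000999 for each, the smallest possible).

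Promoter summits carried some core promoter and insulator motifs more often than promoters with no relaxed peak. Within 100 bp of the summit, 15 of 21 motifs passed Fisher's exact test, 8 more often and 7 less often. Only 8 passed against promoter summits of the relaxed list outside the optimal list, and 8 against 4438 controls matched on GC content. Promoter summits averaged 35.2% GC and the unmatched control promoters 40.9%. Ohler motif 7 (CAKCNCTR) matched at 22.1% of 2550 promoter summits and 6.51% of 8861 control promoters (odds ratio 4.07, adjusted p = 1.95e-99, Fisher's exact test). Its reversed consensus, run as a composition control, did not pass (odds ratio 1.15). The CTCF core, the motif of an insulator protein, matched at 1.02% and 0.135% (odds ratio 7.60, adjusted p = 5.81e-09, Fisher's exact test). The DRE, bound by Dref, matched at 7.18% and 1.92% (odds ratio 3.95) and Motif 1, bound by M1BP, at 3.53% and 0.903% (odds ratio 4.02). Both reversed consensus sequences also passed, with odds ratios of 4.53 and 4.19, but both motifs stayed more frequent than in shuffled peak sequences of the same dinucleotide content (16.4 and 46.6) and in GC-matched controls (2.60 and 3.15). Only 0.0784% of the shuffled sequences matched Motif 1, so its 46.6 rests on very few matches. Against promoter summits of the relaxed list outside the optimal list the odds ratios were lower, at 1.83 for Ohler motif 7, 2.72 for the CTCF core and 1.29 for the DRE (adjusted p = 4.88e-20, 0.00433 and 0.0302, Fisher's exact test), and 0.911 for Motif 1 (adjusted p = 0.685). The CTCF core was at 22.8 against GC-matched controls, but only 0.0451% of these matched, so the ratio rests on very few control matches. Matches were counted on either strand anywhere in the window, and promoter summits had a median position of -107 bp. Many windows thus ended before the transcript start, so presence of a motif at its core promoter position was not tested. The Initiator (15.1% against 25.1%, odds ratio 0.528) and the TATA box (4.39% against 6.88%, odds ratio 0.621) matched less often in these windows. Both lost their call against shuffled peak sequences (0.939 and 0.930, adjusted p = 0.768 and 0.838, Fisher's exact test) and kept it against GC-matched controls (0.599 and 0.533). The reversed consensus of the Initiator was also less frequent (0.826), while that of the TATA box was more frequent (1.87). Against relaxed promoter summits the TATA box ratio turned to 1.22. The BEAF-32 core was more frequent (39.5% against 26.5%, odds ratio 1.82), as was its reversed consensus (1.29). Odds ratios of Ohler motif 6 (1.63), the E-box of Ohler motif 5 (1.27) and poly(dA:dT) (1.30) lay within the 0.711 to 1.67 that motifs not inserted gave in simulated data. GAGA (0.747), less frequent at summits, lay within it too. DPE, the CA repeat, Zelda and Grainyhead matched less often, at odds ratios from 0.226 to 0.595, and these 4 and GAGA each lost the call or turned with another comparison set. Su(Hw), NF-Y, Pho, the Myc and Twist E-boxes and E2F did not pass. Of these, NF-Y passed with a 200 bp window (0.784, adjusted p = 0.0421, Fisher's exact test) and with the 50% of peaks of higher signal (0.568, adjusted p = 0.0259), the Myc E-box with a 200 bp window (1.27, adjusted p = 0.0251), and E2F against shuffled sequences (2.06, adjusted p = 0.0101). Those of the Myc E-box and E2F turned direction, from 0.993 and 0.830.

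Peaks followed arm length closely except on 2 large arms and chromosome 4. Chromosome 4 held 18 IDR peaks where 49.8 were expected from length (exact binomial test, two-sided, adjusted p = 2.07e-06). Arm 2R held 844 against 933.2 (adjusted p = 0.00321) and 2L held 934 against 867.8 (adjusted p = 0.0286, exact binomial test). With the 50% of peaks of higher signal the 2R ratio was 0.911, close to the 0.904 of all peaks, though with fewer peaks it did not pass (adjusted p = 0.0658, exact binomial test). With the expectation taken from transcript starts, the ratio for 2L turned to 0.981, while X was at 1.14 times its expectation (adjusted p = 8.36e-05, exact binomial test) and 3L at 1.07 times (adjusted p = 0.0351). On the dm3 build the optimal list held 4629 peaks, and 18.6% of them were on X, as on dm6.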

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

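Of the tests in this part, those on repeat-free sequence, base composition, open promoters and nearby transcript starts were chosen after the results or closely related values had been seen. The tests on transcription and on extra copies were set before, except that the comparisons of tRNA genes with other non-coding genes, and the limits used to read them, were chosen after.

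The pooled relaxed list on dm3 held 45 peaks outside the main arms, which the report's comparisons do not use. They were picked out by a fixed rule, a count above the 3 that a count of 0 allows. Nothing predicts 0 here, as the relaxed dm3 lists of the 3 replicates held 47, 91 and 76 such peaks, so the rule says only that such peaks exist. Of the 45, 43 were on heterochromatic contigs and 2 on unplaced sequence, and 1 peak of the dm3 optimal list was on such a contig.

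The first pattern is the concentration of summits at promoters. Repeat-free sequence is argued against, since the promoter share was 3.58 times that of random positions in sequence not soft-masked. Soft-masking marks repeats, and how uniquely reads align was not tested. Base composition is argued against too: summits averaged 34.98% GC and random positions 42.1%, but the share was 3.96 times that of random positions matched on GC. A recovery of any open promoter regardless of signal would leave the share flat, and it was 1.31 times higher in the strongest peaks than in the weakest, with exact intervals apart. Recovery that grows with how open a promoter is stays a possible explanation, since neither openness nor the control was analysed here, and no biological explanation was tested, as the design has 1 group.

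The second pattern is the enrichment of some gene lists. Unspecific recovery of highly transcribed genes could produce it, and cannot be told apart from binding here. The tRNA genes were low (odds ratio 0.218), which met the bound set beforehand against this explanation. The simulated 0.242 cannot judge that bound, since simulated promoter peaks were placed only at protein-coding starts. Since the comparison behind the bound is mostly with protein-coding genes, it was not taken to decide. Held against other non-coding genes, tRNA genes were at 0.769 (95% interval 0.409 to 1.34) among IDR peaks. That interval holds 1, so this value decides nothing. The simulation gave 1.21 here, with the same limit, so it was not used as a reference. In the pooled relaxed list tRNA genes were at 2.40, which goes with the explanation. The cytosolic ribosomal protein genes, also highly transcribed, were the most enriched list at 5.54, and transcription was not analysed here.

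The third pattern is the number of relaxed peaks around Chrac-16 itself, where extra copies in the tagged line might raise the count. There were 19 within 20 kb, against a 95th percentile of 18 over all protein-coding genes, a gap smaller than the counting spread of 4.36. Among 3843 genes with a similar number of transcript starts nearby, 94.2% had fewer. The 95th percentile among these genes was 19, so the count was at that limit too. Extra copies and a dense neighbourhood cannot be told apart at this count.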

How the results depend on the processing

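The comparisons with peaks moved to random promoters or genes, with GC-matched control promoters, with other non-coding genes and, for correlation, with the pooled relaxed list were chosen after the data were seen. Of 703 values under alternatives, 565 kept their direction and side of the threshold or stayed within the spread, 48 lost a call, 20 gained one, 10 moved and 60 turned. Of the 60, 45 belong to results that had not passed the main test, and 2 of these 45 passed in the other direction. They were E2F with shuffled sequences (2.06) and the Myc E-box with a 200 bp window (1.27). The other 15 belong to results that had passed, and 5 of these passed in the other direction. They were GAGA with shuffled sequences (6.40) and a 200 bp window (1.21), and the CA repeat with shuffled sequences (5.18). The others were 5' UTR with promoters assigned last (2.12) and tRNA genes against other non-coding genes in the relaxed list (2.40). The promoter share stayed above its comparison in each alternative, from 41.1% at 250 bp to 62.5% in the 1000 strongest peaks. IDR peaks found in all replicates went from 74.6% to 99.7% with the whole relaxed lists and to 61.1% with 50% reciprocal overlap. They went to between 80.8% and 81.0% without 1 replicate, which follows from asking for 2 replicates. Without 1 replicate the rank correlation is that of the 1 pair left, from 0.808 to 0.831, the same values as in the results above. The mean over pairs was 0.821 across IDR peaks and 0.793 across the pooled relaxed list. The median summit position was -92 bp within 250 bp, as the narrower limit implies.

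The count of motifs past the test fell from 15 to 8 both with relaxed promoter summits and with GC-matched controls. Among motifs past the main test, odds ratios turned with relaxed promoter summits for Motif 1 (0.911), Ohler motif 6 (0.894), the E-box (0.963) and the TATA box (1.22), and with a 50 bp window for the E-box (0.939). They turned for GAGA with a 200 bp window (1.21), shuffled sequences (6.40) and GC-matched controls (1.32), for the CA repeat (5.18) and DPE (1.11) with shuffled sequences, and for poly(dA:dT) with GC-matched controls (0.928). Assigning promoters last turned the ratios of 5' UTR (2.12) and intron (1.03), and expectation from transcript starts turned 2L (0.981) and, not past the test, 3R (1.01). The cause was not tested. Of 441 gene list values 28 lost and 15 gained their call. Among lists past the test 1 value turned, that of the tRNA genes against other non-coding genes with the pooled relaxed list (2.40). Among lists not past it 25 of 225 values turned. For Hox genes these were 0.654 at 250 bp, 0.979 at 1000 bp, 0 with the 50% of peaks of higher signal, 0.666 with peaks found in all replicates, 0.515 without soft-masked summits, 0.510 in replicate 2 alone, 0.874 with moved peaks and, without 1 replicate, from 0.611 to 1.43. Proteasome genes were at 1.21 at 250 bp, 1.69 in the relaxed list, 1.16 with shared promoters counted once, 1.18 and 1.16 in replicates 1 and 3 alone and 1.38 with moved peaks. Muscle genes were at 1.14 with the 50% of peaks of higher signal, 1.52 in the relaxed list, 1.104 with shared promoters counted once and, without 1 replicate, from 0.754 to 1.08. The subunit genes were at 0.979 at 1000 bp and 0 with the 50% of peaks of higher signal, heat shock genes at 0.561 in the relaxed list and 0.945 in replicate 3 alone, dosage compensation genes at 1.70 in the relaxed list and snRNA genes at 0.844 at 250 bp.

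Motifs not past the main test that turned were Su(Hw) (0.910 at 50 bp, 0.872 at 200 bp, 0.961 shuffled, 0.869 GC-matched), Pho (1.12 at 200 bp and shuffled, 1.12 with relaxed summits, 1.02 without soft-masked summits, 1.09 GC-matched), NF-Y (1.11 shuffled) and the Twist E-box (0.95002 with relaxed summits, 0.982 shuffled). The Myc E-box was also at 1.104 with the 50% of peaks of higher signal, 1.01 without soft-masked summits and 1.15 GC-matched, and E2F at 1.19 at 200 bp and 1.09 GC-matched. The list of subunit genes has no finite odds ratio with the pooled relaxed list, where 4 of 4 genes have a peak. No paired analysis was possible because there is 1 group. Depth is unknown.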

Other observations

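The values in this part were all looked for after the results above were seen. At the 2391 IDR summits away from promoters, the CTCF core matched at 1.80% of windows and at 0.293% of windows 600 bp to one side (Fisher's exact test over 21 motifs, odds ratio 6.24, adjusted p = 3.85e-06). The Su(Hw) motif, of another insulator protein, matched at 1.59% and 0.753% (odds ratio 2.13, adjusted p = 0.0300, Fisher's exact test). In all 7 of the 21 motifs passed there: the TATA box (odds ratio 1.64) and poly(dA:dT) (1.38) were also more frequent at summits, and the E-box of Ohler motif 5 (0.647), GAGA (0.514) and the CA repeat (0.498) less. The DRE matched at 0.376% of both. The only comparison here was with these flanking windows, which were not matched on GC content. Summits away from promoters averaged 34.7% GC, so base composition may bear on these calls.

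Among promoter summits the DRE became rarer as signal rose, from 9.34% (exact interval 7.10 to 12.01) of the 578 weakest to 4.64% (exact interval 3.25 to 6.39) of the 755 strongest. Motif 1 went from 5.36% (exact interval 3.67 to 7.53) to 1.85% (exact interval 1.02 to 3.09) between the same sets. The fall was not particular to them. The BEAF-32 core, a part of the DRE sequence, went from 45.7% (exact interval 41.6 to 49.8) to 31.4% (exact interval 28.1 to 34.8). With intervals that overlap, Ohler motif 7 went from 23.7% to 18.9% and NF-Y from 3.29% to 1.19%, while poly(dA:dT) rose from 11.8% to 15.9%.

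Of the 2266 words of 8 bases tested at summits away from promoters, CACTGAGA had the highest odds ratio among the 25 with the smallest p. It occurred within 50 bp of 2.17% of these summits and in 0.146% of windows 400 bp to either side (odds ratio 15.2, adjusted p = 6.76e-16, Fisher's exact test). CACTGAGA was picked because of its value, and which protein binds it was not analysed here. Most of the 25 words consisted only of A and T, such as TATTTTAA (5.23% and 1.15%, odds ratio 4.74).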
